A study of Homo sapiens with 8 samples.

How the data were processed

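Gene expression was measured on 8 Affymetrix HG-U133 Plus 2.0 arrays of human umbilical vein endothelial cells, 2 for each of 4 groups: unstimulated, Borrelia burgdorferi, interferon gamma (IFN-gamma), and both. The deposited table gives an intensity per probe set and array, made by robust multi-array averaging (RMA) per the submitters' processing notes, with a software version not given in the sources used here. The values were linear and positive, and log2 was taken without a pseudocount. Array medians lay between 4.81 and 4.92 on the log2 scale and the highest intensities between 14144 and 21662, so the arrays did not share 1 distribution.

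The table held 54675 probe sets, of which 62 were controls, 41091 named 1 gene symbol, 1801 several and 11721 none. Only probe sets with 1 symbol were used, and for the 10511 genes with several probe sets the one with the highest mean over the 8 arrays was kept, which left 19740 genes. XIST, TSIX and Y-linked genes were left out. Genes are identified by symbol and probe set, and no genome build was needed.

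limma 3.58.1 (lmFit and eBayes, without trend, in R 4.3.3) fitted all 8 arrays in 4 groups with 4 residual degrees of freedom. The 6 comparisons were each stimulus and both against none, both against each single stimulus, and the interaction, which is the change with both stimuli less the sum of the single changes. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. The 23 gene lists, the tests, the first set of other settings and the rule for naming genes were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 138 tests. Counts adjusted over the list alone repeat the gene tests with adjustment within each list.

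The naming rule took the called genes with the largest changes in each comparison, up to 4 called members of each list, and a fixed set of chemokines, adhesion molecules and immune regulators whether called or not. Members named because they passed when adjusted over the list alone, such as CD74, CTSS, HLA-DMB, CASP10, SOD2, TNFAIP2 and the metallothioneins, were chosen after their values were seen.

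The experiment files place the A arrays in 1 hybridization session and the B arrays in another, so a block for the session and a block for the replicate letter are the same fit, with 3 residual degrees of freedom. The block leaves the log2 change as it is and alters its error. It assumes 1 difference between sessions common to all groups. Across probe sets, the A arrays' deviations from their group means correlated with r = 0.49 to 0.7 among the unstimulated, Borrelia and IFN-gamma groups. The group with both stimuli gave r = -0.06, 0.18 and 0.09 with these groups, so it did not share that difference. Other settings of that first set were a filter on low signal, renewed quantile normalization, median centring, an intensity trend, other uses of the probe sets, the compared groups alone, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups. After the data were seen, a covariate for the 3' to 5' difference of the GAPDH and ACTB control probe sets, array weights, and a fit without the 2 arrays of highest 3' to 5' difference were added.

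The fit was tested on simulated data with 50 changed genes at each size. It recovered 0 at a log2 change of 1, 24 at 2, 43 at 4 and 49 at 6, and called 5 unchanged genes. The simulated noise was independent between genes and arrays, with no session, chip lot or RNA integrity effect. These counts are therefore not the sensitivity on the real arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.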

Results

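Transcript levels were measured in human umbilical vein endothelial cells (HUVEC), primary cells from the inner lining of a vein that are widely used as a model of the blood vessel wall. The cells were left unstimulated, exposed to Borrelia burgdorferi (the spirochete that causes Lyme disease), treated with interferon gamma (IFN-gamma, a cytokine of T cells and natural killer cells), or given both. Each of the 4 groups had 2 Affymetrix HG-U133 Plus 2.0 arrays, a 1-colour platform, lettered A and B in the labels, and this number of arrays limits the precision of every value. The experiment files place all A arrays in 1 hybridization session and all B arrays in another, so each comparison is given over both sessions and within each. They also name 3 chip lots: unstimulated array A had a lot of its own, the other A arrays shared another, and the B arrays shared the last. Every session A comparison with unstimulated cells is therefore also a comparison between lots, which the session block does not remove. No label says whether A and B were separate cultures, so the p-values measure only the spread between these arrays. A total of 19740 genes were tested, and values are log2 of the deposited intensities unless a fold is stated.

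RNA integrity differed between the arrays. The array carries control probe sets at the 3' and 5' ends of GAPDH and ACTB transcripts, and a high 3' over 5' ratio is a sign of degraded or incompletely copied RNA. The GAPDH ratio was 3.31 and 1.25 on the unstimulated arrays A and B and 2.24 and 2.91 with Borrelia. With IFN-gamma alone it was 59.7 on array A and 1.1 on array B, and with both stimuli it was 15.2 and 13.4. Across all 54675 probe sets, the 2 unstimulated arrays correlated with r = 0.89, as did the 2 IFN-gamma arrays. The Borrelia pair reached 0.96 and the pair with both stimuli 0.95 (correlations across probe sets, which are not independent replicates). Unstimulated array B correlated more closely with Borrelia array B (0.985) and IFN-gamma array B (0.98), of its own session and lot, than with unstimulated array A.

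**Figure D1:**
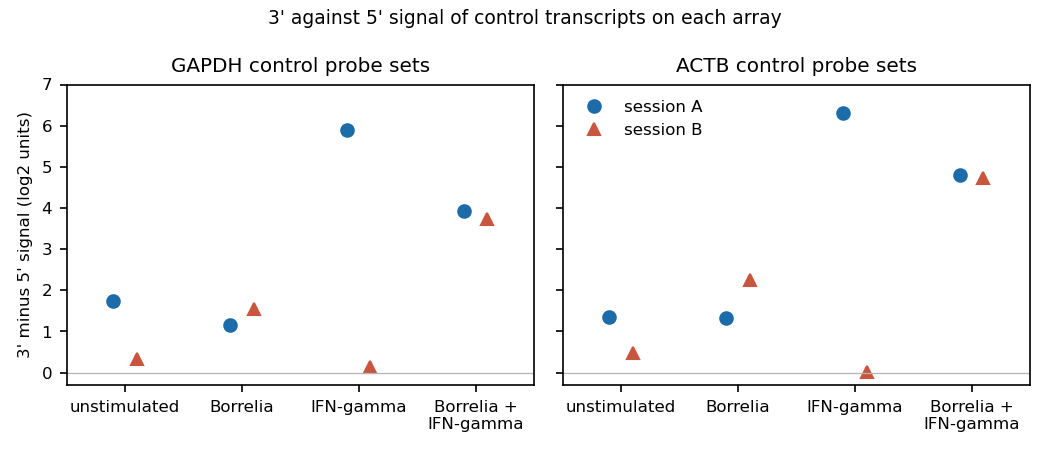
Difference between 3' and 5' signal (log2 units, vertical axis) of the GAPDH and ACTB control probe sets on each of the 8 arrays, by group; circles are session A and triangles session B. The IFN-gamma array of session A and both arrays with Borrelia and IFN-gamma lie above all others.

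The first question was what the bacterium alone did to the endothelium. The largest increases with Borrelia were in neutrophil chemoattractants and leukocyte adhesion molecules. CXCL8 (interleukin 8) was 20.4-fold higher, with a log2 difference of 4.35 ± 0.35 (SE, 2 arrays per group), and 4.43 in session A and 4.27 in session B. SELE (E-selectin, which captures rolling leukocytes) differed by 4.33 ± 0.59, VCAM1 (a ligand for leukocyte integrins) by 4.05 ± 0.59, CXCL1 by 3.66 ± 0.41 and CXCL2 by 3.54 ± 0.60, each by at least 2-fold in both sessions. None of these passed the test over all genes. The adjusted p from limma was 0.0838 for CXCL8, 0.373 for CXCL1, 0.906 for SELE and 1 for VCAM1 and CXCL2. ICAM1 differed by 1.64 ± 0.48, CCL2 by 1.38 ± 0.44, IL6 by 1.02 ± 0.43 and CX3CL1 by 1.10 ± 0.58, all with an adjusted p of 1. The chemokines of interferon responses stayed near the unstimulated level, with differences of 0.15 ± 0.40 for CXCL9, 0.07 ± 0.28 for CXCL10 and 0.17 ± 0.31 for CXCL11. CXCL3 differed by 1.46 ± 0.32 and MMP1 by 0.56 ± 0.31, and CCL5 (-0.01 ± 0.27), CXCL5 (-0.11 ± 0.28), CXCL6 (0.28 ± 0.33) and CSF3 (0.06 ± 0.40) lay near 0, all with an adjusted p of 1. The value of CXCL2 rests on 1 of its probe sets, since its 2 others gave 0.15 and 0.45, while the other probe set of CXCL8 gave 2.96 and that of CX3CL1 2.32. The 2 others of ICAM1 gave 0.61 and 2.38.

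As groups, 6 of the 23 fixed lists were higher with Borrelia by camera, a test of a list against all other genes. Of the 8 neutrophil chemoattractants, 7 were higher, with a median of 0.87 (0.60 in session A and 1.41 in session B). The camera adjusted p was 5.92e-18, and 4 members, among them CXCL8, CXCL1 and CXCL2, passed when adjusted over the list alone. With a correlation between genes estimated from the data, that list gave an adjusted p = 0.0868. Of the 25 NF-kappaB targets and feedback genes, 24 were higher, with a median of 0.73 (0.77 and 0.64 in sessions A and B; camera adjusted p = 9.86e-22, and adjusted p = 0.193 with an estimated correlation). TNFAIP3, which shuts down NF-kappaB signalling, differed by 1.98 ± 0.61 and NFKBIA, the inhibitor IkappaB-alpha, by 1.52 ± 0.50, with 0.25 on its other probe set. None of that list passed when adjusted over the list alone, but 4 did with the session as a block. Of the 16 adhesion and transmigration genes, 12 were higher, with medians of 0.60 in session A and 0.21 in session B (camera adjusted p = 4.87e-09, and adjusted p = 0.215 with an estimated correlation). SELE and VCAM1 were the 2 members that passed when adjusted over the list alone. Oxidative stress and metallothionein genes (13 of 14 higher, median 0.30; camera adjusted p = 1.83e-06), T cell and monocyte chemoattractants (11 of 14, median 0.15; 0.00187) and matrix proteases (8 of 15, median 0.13; 0.00787) also shifted up. Their adjusted p was 0.193, 0.268 and 0.215 with an estimated correlation, and no member passed when adjusted over the list alone. Within sessions A and B the medians of these 3 lists were 0.47 and 0.21, 0.15 and 0.25, and 0.09 and 0.12.

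Over all genes, limma called 0 genes for Borrelia against no stimulus, with 28 genes at an unadjusted p under 0.05. With the replicate letter as a block 0 genes were called and 131 had an unadjusted p under 0.05. Renewed quantile normalization called 1 gene, CXCL8, with an adjusted p of 0.0136. Array weights with the block called 4, CXCL8 (0.00266), VCAM1 (0.011), CXCL1 (0.0262) and SELE (0.0262). In session A 946 genes were at least 2-fold higher with Borrelia and in session B 45, and 19 genes were so in both. The session A count also compares 2 chip lots. Without unstimulated array B the camera adjusted p was 0.502 for the T cell and monocyte chemoattractants and 0.198 for the matrix proteases, and without Borrelia array A it was 0.0769 and 0.0558. Without unstimulated array A that of the oxidative stress genes was 0.169.

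The second question was what IFN-gamma alone did. Among the largest increases were those of chemokines that attract activated T cells and share the receptor CXCR3. CXCL11 rose 229.7-fold (7.84 ± 0.31, adjusted p = 0.000252), CXCL10 rose 179-fold (7.48 ± 0.28, adjusted p = 0.000252) and CXCL9 rose 78.2-fold (6.29 ± 0.40, adjusted p = 0.00367). The unstimulated level of CXCL11 lay below the array medians, so its fold is approximate and may be understated. IDO1, which breaks down tryptophan, rose by 6.88 ± 0.54 and the monocyte chemoattractant CCL8 by 4.14 ± 0.26. The transcription factor IRF1 (4.50 ± 0.36), the peptide transporter TAP1 (4.19 ± 0.28), the guanylate-binding protein GBP5 (4.76 ± 0.46), EPSTI1 (4.55 ± 0.48), PLAAT4 (4.31 ± 0.29), the B cell survival factor TNFSF13B (4.28 ± 0.29) and the matrix proteoglycan VCAN (3.35 ± 0.33) were also called. The other probe set of EPSTI1 gave 2.19 and that of CXCL11 8.22. With the 3' to 5' covariate GBP5 differed by 4.47 ± 0.47 and its limma call ended (adjusted p = 0.0946), while the other calls named here were kept. CXCL10 differed by 7.51 in session A and 7.46 in session B. IDO1 had the widest gap of these genes, with 6.40 and 7.36.

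Of the genes that had stood out with Borrelia, CXCL8 differed with IFN-gamma by -0.93 ± 0.35, SELE by -0.23 ± 0.59 and CXCL1 by 0.21 ± 0.41, each with an adjusted p of 1. VCAM1 and CXCL2, which had also stood out, were higher by 2.62 ± 0.59 and 2.59 ± 0.60, CX3CL1 (fractalkine) by 2.48 ± 0.58 and CD274 (PD-L1) by 3.01 ± 0.40 without passing the test, with adjusted p-values of 0.877, 0.925, 0.927 and 0.122. The 2 other probe sets of CXCL2 gave 0.29 and 0.64, that of CD274 1.1 and that of CX3CL1 3.49. CIITA, the activator of MHC class II genes, differed by 0.07 ± 0.41 on the probe set tested and by 0.11 and 1.34 on its 2 others.

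**Figure D2:**
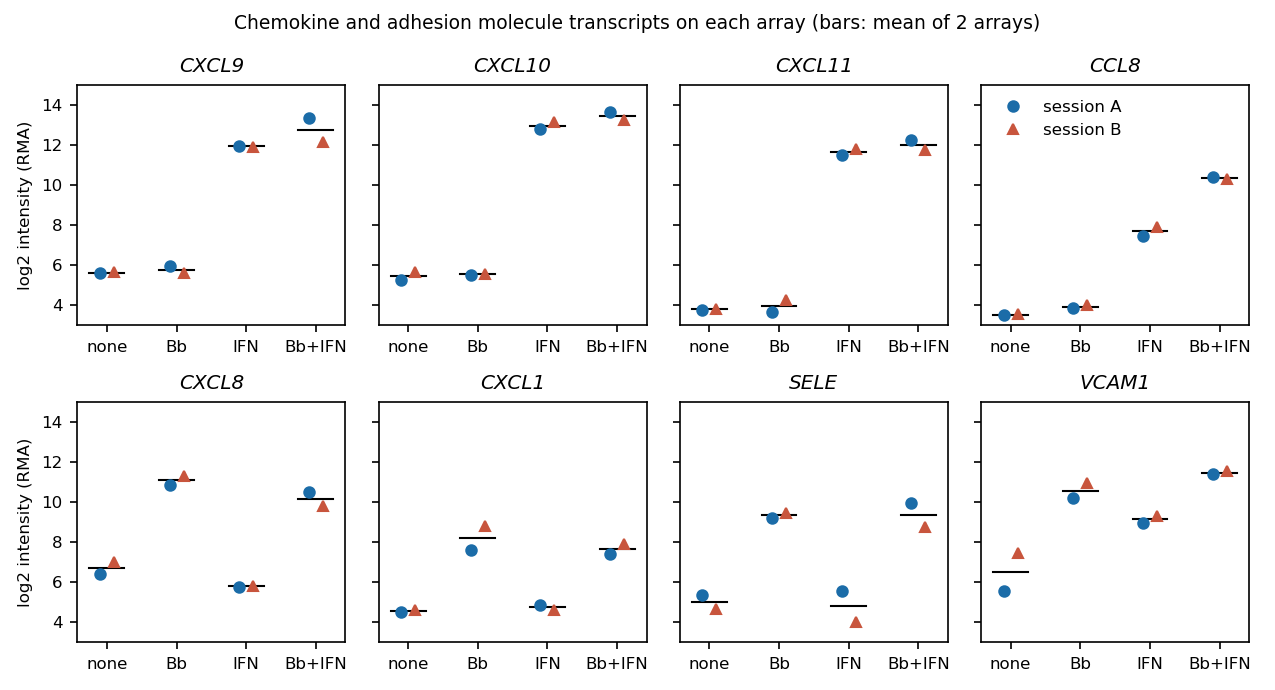
Log2 RMA intensity (vertical axis) of 8 chemokine and adhesion molecule transcripts on each array, for no stimulus, Borrelia (Bb), IFN-gamma (IFN) and both; circles are session A, triangles session B and bars the mean of 2 arrays. CXCL9, CXCL10 and CXCL11 are high on the 4 arrays with IFN-gamma, CXCL8, CXCL1 and SELE on the 4 arrays with Borrelia, and CCL8 is highest with both.

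Among the fixed lists, 30 of 34 IFN-gamma response genes were higher, with a median of 2.44 (2.23 in session A, 2.36 in session B; camera adjusted p = 5.03e-62, and adjusted p = 0.0868 with an estimated correlation). Over all genes 5 of them were called and 28 passed when adjusted over the list alone. Of 39 type I interferon-stimulated genes 38 were higher (median 1.48, sessions 1.25 and 1.61; camera adjusted p = 1.16e-38, and adjusted p = 0.215 with an estimated correlation), 1 was called and 17 passed when adjusted over the list alone. Of 14 T cell and monocyte chemoattractants 4 were called over all genes, CXCL9, CXCL10, CXCL11 and CCL8, and 5 passed when adjusted over the list alone. The list had a median of 0.18 (0.42 in session A and 0.61 in session B), a camera adjusted p of 8.6e-15, and adjusted p = 0.0868 with an estimated correlation. Antigen presentation shifted up as well. In the MHC class I list 18 of 20 genes were higher (median 0.79, sessions 0.93 and 0.86; camera adjusted p = 2.36e-15, and adjusted p = 0.215 with an estimated correlation). TAP1 was called there, and 3 members passed when adjusted over the list alone, or 7 with the block. In the MHC class II list 12 of 16 genes were higher (median 0.80, sessions 0.66 and 0.57; camera adjusted p = 2.97e-06, and adjusted p = 0.181 with an estimated correlation). CD74 (the invariant chain, 2.05 ± 0.37), CTSS (cathepsin S, 1.76 ± 0.35) and HLA-DMB (1.04 ± 0.27) passed when adjusted over the list alone, a count of 3 that became 6 with the block. The 2 other probe sets of CD74 gave 0.11 and 0.29, and those of CTSS 1.29 and 1.44.

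Cholesterol synthesis genes shifted down (12 of 13 lower, median -0.34, sessions -0.44 and -0.46; camera adjusted p = 0.00227, and adjusted p = 0.268 with an estimated correlation), and so did endothelial markers (14 of 16 lower, median -0.31, sessions -0.16 and -0.47; 0.00223, and adjusted p = 0.405 with an estimated correlation). No member of either passed when adjusted over the list alone. With the 3' to 5' difference as a covariate the adjusted p of the endothelial markers was 0.181, and with the covariate and the session block 0.0195. Apoptosis genes were higher in 10 of 15 (median 0.19, sessions 0.39 and 0.17; camera adjusted p = 0.027, 0.0501 with the block, and adjusted p = 0.248 with an estimated correlation), and 1, CASP10, passed when adjusted over the list alone. It differed by 1.98 ± 0.30, with 0.73 to 0.91 on its other probe sets.

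In all, limma called 14 genes for IFN-gamma against no stimulus, all higher, and 28 with the replicate letter as a block, which kept all 14. At least 2-fold in both sessions, 142 genes were higher and 27 lower. The count was 4 without IFN-gamma array B, 7 without IFN-gamma array A and 9 without either Borrelia array or either array with both stimuli, and CXCL11, CXCL10, TNFSF13B and CCL8 were called whichever array was left out. The fit to these 2 groups alone called 3 genes, and 0 were called without IFN-gamma array A and array A with both stimuli, where 212 had an unadjusted p under 0.05. Leaving out 1 array ended the MHC class II shift (0.0989 without IFN-gamma array B), the cholesterol shift (0.376 without unstimulated array B), the endothelial marker shift (0.724 without unstimulated array B, 0.387 without IFN-gamma array A) and the apoptosis shift (0.35 without unstimulated array B, 0.16 without IFN-gamma array B).

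The cells given both stimuli were then compared with unstimulated cells. CXCL11 rose by 8.19 ± 0.31, CXCL10 by 7.96 ± 0.28, CXCL9 by 7.11 ± 0.40 and IDO1 by 6.40 ± 0.54. CCL8 rose 114-fold (6.83 ± 0.26, adjusted p = 0.000124, with 6.92 in session A and 6.73 in session B). The unstimulated level of CCL8 lay below the array medians, so this fold is approximate and may be understated. CXCL8 rose 10.7-fold (3.42 ± 0.35, adjusted p = 0.0286), although the gene's other probe set gave 0.65. CD274 rose by 3.43 ± 0.40 (adjusted p = 0.0492), with 0.77 on its other probe set. With the 3' to 5' covariate the log2 differences were 3.48 ± 0.46 for CXCL8 and 3.58 ± 0.52 for CD274, and the wider error ended both calls (adjusted p = 0.244 and 0.271). Both calls were made in 1 of the 8 fits that left out an array. IRF1 (5.15 ± 0.36), GBP5 (4.83 ± 0.46), PLAAT4 (4.55 ± 0.29), the phospholipase PLA1A (4.50 ± 0.52), TAP1 (4.49 ± 0.28), EPSTI1 (4.39 ± 0.48), TNFSF13B (4.25 ± 0.29) and NLRC5, an activator of MHC class I genes (3.27 ± 0.32), were also called. The covariate ended the limma calls of GBP5 (adjusted p = 0.192), EPSTI1 (0.0843) and NLRC5 (0.234) too. It kept those of IRF1, PLAAT4, PLA1A, TAP1 and TNFSF13B.

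VCAM1 (4.95 ± 0.59, adjusted p = 0.0576), CXCL2 (4.86 ± 0.60, 0.0628), CX3CL1 (4.63 ± 0.58, 0.0641), SELE (4.33 ± 0.59, 0.0878) and CXCL1 (3.11 ± 0.41, 0.0795) lay just outside the threshold and were called with the block, at 0.0113, 0.0153, 0.00996, 0.0149 and 0.0261. NFKBIA (2.29 ± 0.50, adjusted p = 0.505) was called with the block too, at 0.0311, with 0.57 on its other probe set. The 2 others of CXCL2 gave 0.56 and 0.59 and that of CX3CL1 5.90. ICAM1 differed by 2.26 ± 0.48 and CCL2 by 1.79 ± 0.44 without being called in either fit. The block assumes a session difference common to all groups, which the arrays with both stimuli did not share. Calls made only with the block are therefore uncertain here.

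Most lists that had shifted with either stimulus shifted with both. The exceptions were adhesion genes (8 of 16 higher, median 0.00, sessions 0.18 and 0.08; camera adjusted p = 0.237, and adjusted p = 0.73 with an estimated correlation) and matrix proteases (8 of 15 lower, median -0.06, sessions 0.03 and -0.16; 0.615, and adjusted p = 0.767 with an estimated correlation). Of these, 3 and 0 members passed when adjusted over the list alone. T cell and monocyte chemoattractants were higher in 13 of 14 (median 1.67, sessions 2.15 and 1.18; camera adjusted p = 3.62e-25, and adjusted p = 0.0868 with an estimated correlation), 4 were called and 9 passed when adjusted over the list alone. All 8 neutrophil chemoattractants were higher (median 0.87, sessions 0.79 and 0.99), but CXCL6 by only 0.03 ± 0.33 and CXCL5 by 0.25 ± 0.28. The mean intensities of CXCL6 and CXCL5 with both stimuli were 8.6 and 14.1, below the array medians of 28.04 to 30.36. The list gave a camera adjusted p of 2.05e-08, and adjusted p = 0.0868 with an estimated correlation. CXCL8 was called and 4 members passed when adjusted over the list alone. IFN-gamma response genes were higher in 31 of 34 (median 2.63, sessions 2.76 and 2.05; 1.34e-46, and adjusted p = 0.0868 with an estimated correlation), with 7 called and 23 adjusted over the list alone. Type I interferon-stimulated genes (38 of 39 higher, median 1.49, sessions 2.00 and 1.04; 5.1e-29), MHC class I genes (17 of 20, median 0.93, sessions 1.21 and 0.67; 3.41e-12) and NF-kappaB targets (21 of 25, median 0.98, sessions 0.95 and 1.12; 9.12e-13) each had an adjusted p = 0.248 with an estimated correlation. Adjusted over the list alone, 16, 8 and 9 of their members passed, among them SOD2 (mitochondrial superoxide dismutase, 5.54 ± 0.99) and TNFAIP2 (3.02 ± 0.45, with 0.40 on its other probe set). MHC class II genes were higher in 15 of 16 (median 1.02, sessions 1.20 and 0.59; 4.14e-07, and adjusted p = 0.156 with an estimated correlation), with 3 adjusted over the list alone and 8 with the block. Cytokines of immune cells (median 0.25, sessions 0.23 and 0.42; 0.00454), apoptosis genes (0.52, sessions 0.43 and 0.42; 0.00833) and oxidative stress genes (0.35, sessions 0.84 and 0.09; 0.00334) were higher too, with adjusted p-values of 0.193, 0.215 and 0.273 with an estimated correlation. In these lists 1, 0 and 0 members were called, and 3 higher and 1 lower, 1 higher and 5 higher passed when adjusted over the list alone. The 5 included the metallothioneins MT1X (1.22 ± 0.24), MT1F (1.07 ± 0.23) and MT1G (1.03 ± 0.24).

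**Figure D3:**
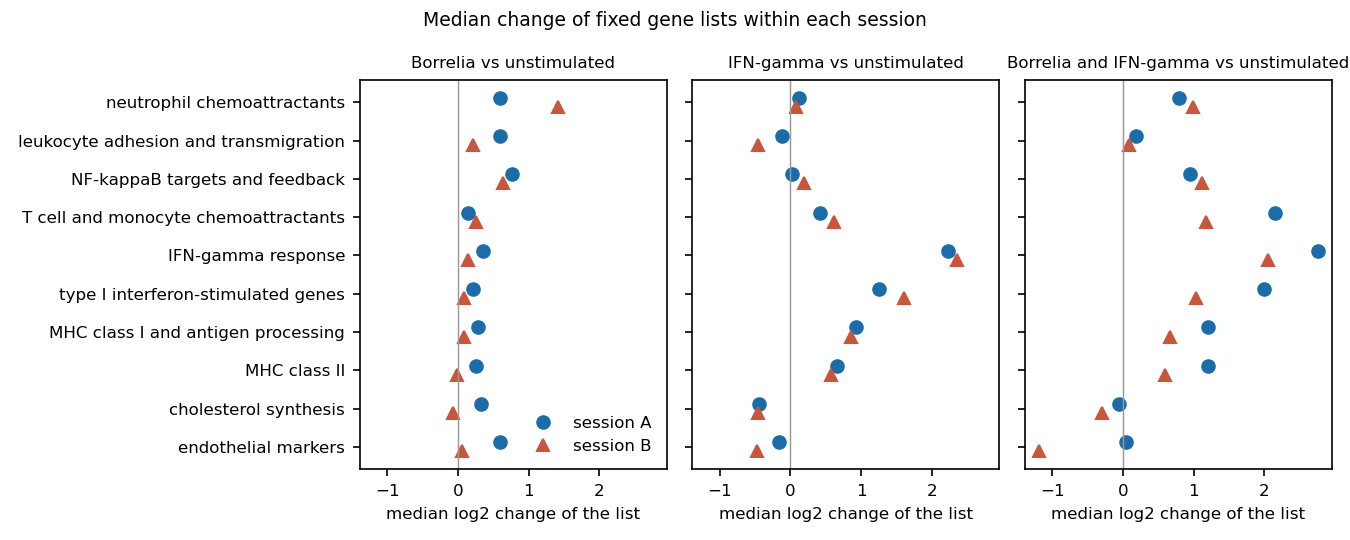
Median log2 change (horizontal axis) of 10 fixed gene lists against unstimulated cells with Borrelia, IFN-gamma or both, within session A (circles) and session B (triangles). The IFN-gamma response list reaches 2.23 and 2.36 with IFN-gamma, and the endothelial marker list with both stimuli lies at 0.04 in session A and -1.19 in session B.

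Endothelial markers (14 of 16 lower, median -0.42; camera adjusted p = 3.99e-05), cell cycle genes (23 of 30 lower, median -0.30; 0.00324) and cholesterol synthesis genes (10 of 13 lower, median -0.26; 0.00844) shifted down with both stimuli, at adjusted p-values of 0.27, 0.719 and 0.316 with an estimated correlation. No member of these lists passed when adjusted over the list alone. The shifts differed by session, with endothelial medians of 0.04 in session A and -1.19 in session B, cell cycle medians of 0.34 and -0.77, and cholesterol medians of -0.05 and -0.30. Both arrays with both stimuli had a high GAPDH 3' over 5' ratio (15.2 and 13.4). With that difference as a covariate the adjusted p was 0.265 for endothelial markers, 0.271 for cholesterol synthesis, 0.0506 for apoptosis genes and 0.554, in the opposite direction, for the cell cycle. With the covariate and the session block it was 0.0219 for endothelial markers, 0.0911 for cholesterol synthesis, 0.0306 for apoptosis genes and 0.0241, again lower, for the cell cycle.

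Against no stimulus, limma called 20 genes with both stimuli, all higher. In session A 1377 genes were at least 2-fold higher and 407 lower, and in session B 697 and 2135. In both sessions 162 were so higher and 27 lower. Another 486 changed at least 2-fold in opposite directions, 469 of them higher in session A. The session A counts also compare chip lots. With the replicate letter as a block there were 68 calls, 67 higher and 1 lower, which kept the 20. The lower gene was MALL (-1.89), named after its value was seen. The count was 4 without either array with both stimuli, 9 without either Borrelia array, 13 without either IFN-gamma array and 11 without unstimulated array A. With the 3' to 5' covariate it was 10, in the fit to these 2 groups alone 9, and without the 2 A arrays that had received IFN-gamma 0, with 804 genes at an unadjusted p under 0.05. CXCL11, CXCL10, CXCL9 and CCL8 were called whichever array was left out. Leaving out unstimulated array B gave camera adjusted p-values of 0.119 for cytokines, 0.135 for apoptosis, 0.24 for the cell cycle with the direction turned, 0.376 for cholesterol synthesis and 0.193 for endothelial markers. Without unstimulated array A it was 0.518 for oxidative stress genes. Array A with both stimuli decided cytokines (0.0503), cell cycle (0.337) and oxidative stress genes (0.0917), and array B with both stimuli decided cholesterol synthesis (0.0792).

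The next comparison asked what IFN-gamma changed in endothelium that also had Borrelia. The T cell chemoattractants again led, with CXCL11 up by 8.02 ± 0.31, CXCL10 by 7.90 ± 0.28, CXCL9 by 6.96 ± 0.40 and CCL8 by 6.43 ± 0.26, followed by IDO1 (5.98 ± 0.54), GBP5 (4.73 ± 0.46), PLAAT4 (4.56 ± 0.29), IRF1 (4.53 ± 0.36), TNFSF13B (4.35 ± 0.29), TAP1 (3.95 ± 0.28) and NLRC5 (3.62 ± 0.32), all called. With the 3' to 5' covariate limma called 9 genes. It ended the calls of GBP5 (4.35 ± 0.50, adjusted p = 0.144), IRF1 (4.68 ± 0.43, 0.0695) and NLRC5 (3.48 ± 0.38, 0.118) and kept the others named here. CX3CL1 differed by 3.53 ± 0.58 (adjusted p = 0.271) and was called with the block at 0.0297. The transcripts that had stood out with Borrelia were not called between Borrelia with and without IFN-gamma. They differed by -0.93 ± 0.35 for CXCL8, -0.54 ± 0.41 for CXCL1, 0.00 ± 0.59 for SELE, 0.90 ± 0.59 for VCAM1 and 1.31 ± 0.60 for CXCL2 (2.22 in session A and 0.40 in session B), each with an adjusted p of 1. The other probe set of CXCL8 gave -2.31.

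This comparison shares no array with that of IFN-gamma alone. Of the 14 genes called with IFN-gamma alone and the 13 called here, 12 were shared, where independent lists would share 0.01. Both sets of calls use 1 estimate of each gene's spread over all 8 arrays, so they are not independent. Camera called T cell and monocyte chemoattractants (13 of 14 higher, median 0.76, sessions 1.08 and 0.67; adjusted p = 1.85e-19), IFN-gamma response genes (32 of 34, median 2.38, sessions 2.65 and 1.99; 2.16e-43), type I interferon-stimulated genes (38 of 39, median 1.34, sessions 1.57 and 1.06; 8.88e-26), MHC class I genes (17 of 20, median 0.77, sessions 0.91 and 0.61; 7.94e-10) and MHC class II genes (13 of 16, median 0.80, sessions 0.99 and 0.64; 5.01e-07). With an estimated correlation the adjusted p was 0.0868, 0.0868, 0.248, 0.264 and 0.156, and adjusted over the list alone 5, 24, 16, 3 and 3 members passed. Over all genes 4, 5, 0, 2 and 0 members were called. With the block the MHC class I count adjusted over the list alone was 8. NF-kappaB targets (18 of 25 higher, median 0.27, sessions 0.30 and 0.25; 0.0343) and apoptosis genes (12 of 15, median 0.21, sessions 0.15 and 0.39; 0.0336) were slightly higher, with adjusted p = 0.679 and 0.248 with an estimated correlation and 0 and 1 members passing when adjusted over the list alone.

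Endothelial markers shifted down (15 of 16 lower, median -0.67, sessions -0.50 and -1.04; camera adjusted p = 2.97e-06, and adjusted p = 0.248 with an estimated correlation). Cell cycle genes (25 of 30, median -0.41, sessions -0.18 and -0.71; 0.00684), cholesterol synthesis genes (10 of 13, median -0.49, sessions -0.37 and -0.29; 0.00776) and matrix proteases (12 of 15, median -0.31, sessions -0.21 and -0.40; 0.0189) were lower as well, at adjusted p-values of 0.73, 0.312 and 0.248 with an estimated correlation. No member of these 4 lists was called or passed when adjusted over the list alone. The GAPDH 3' over 5' ratio was 15.2 and 13.4 here against 2.24 and 2.91 with Borrelia alone. With the 3' to 5' difference as a covariate, the adjusted p was 0.0101 for endothelial markers, 0.0886 for cholesterol synthesis, 0.0587 for matrix proteases and 0.822, in the opposite direction, for the cell cycle. With the covariate and the session block it was 0.000646, 0.0498 and 0.0481 for these 3 lists, 0.00459, again lower, for the cell cycle, and 0.0609 for apoptosis genes. In all, limma called 13 genes, all higher, and 34 with the replicate letter as a block (33 higher and 1 lower), which kept the 13. The lower gene was TNFSF15, a TNF family cytokine (-2.64, block adjusted p = 0.0297), named after its value was seen. The count was 4 without either array with both stimuli, 4 without Borrelia array A and 7 without Borrelia array B. It was 20 in the fit to these 2 groups alone and 0 without the 2 A arrays that had received IFN-gamma, with 715 genes at an unadjusted p under 0.05. Leaving out 1 array ended the shift of NF-kappaB targets (0.66 without Borrelia array A, 0.334 without array B with both stimuli), of apoptosis genes (0.138 without Borrelia array A, 0.0547 and 0.124 without arrays A and B with both stimuli), of cell cycle genes (0.986 without Borrelia array B, 0.378 without array A with both stimuli), and, without array B with both stimuli, of matrix proteases (0.0991) and cholesterol synthesis (0.0632).

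The reverse comparison asked what Borrelia changed in endothelium treated with IFN-gamma. SELE was higher by 4.55 ± 0.59 and CXCL8 by 4.35 ± 0.35, beside 4.33 and 4.35 for Borrelia alone. On its other probe set CXCL8 was higher by 1.03 here and 2.96 with Borrelia alone. Next were CXCL1 (2.91 ± 0.41), SOD2 (2.79 ± 0.99), CCL8 (2.68 ± 0.26), TNFAIP3 (2.34 ± 0.61), VCAM1 (2.33 ± 0.59), CCL4 (2.31 ± 0.44), CXCL2 (2.27 ± 0.60) and CX3CL1 (2.16 ± 0.58), and NFKBIA differed by 1.75 ± 0.50. The 2 other probe sets of CXCL2 gave -0.08 and 0.30, and those of NFKBIA, TNFAIP3 and CX3CL1, 1 each, gave 0.74, 1.45 and 2.42. None was called, with an adjusted p of 0.0842 for CXCL8, 0.126 for CCL8 and 0.653 for SELE. CXCL9, CXCL10 and CXCL11 differed by 0.82 ± 0.40, 0.48 ± 0.28 and 0.34 ± 0.31, each with an adjusted p of 0.999. The other probe set of CXCL11 gave -0.68. By camera, T cell and monocyte chemoattractants (14 of 14 higher, median 0.51, sessions 1.09 and 0.39; adjusted p = 7.13e-10), neutrophil chemoattractants (7 of 8, median 0.81, sessions 0.91 and 0.77; 1.97e-07), NF-kappaB targets (22 of 25, median 0.92, sessions 1.13 and 0.80; 1.43e-11) and adhesion genes (13 of 16, median 0.26, sessions 0.45 and 0.35; 0.00223) were higher. With an estimated correlation the adjusted p was 0.15, 0.0868, 0.253 and 0.433, and adjusted over the list alone 5, 4, 0 and 2 members passed. With the block 14 NF-kappaB targets did. Oxidative stress genes were higher (median 0.34, sessions 0.39 and 0.29; 0.046, 0.14 with the block, and adjusted p = 0.445 with an estimated correlation) and cell cycle genes lower (median -0.23, sessions 0.06 and -0.35; 0.0278, and adjusted p = 0.767 with an estimated correlation). No member of these last 2 lists passed when adjusted over the list alone. With the 3' to 5' covariate the cell cycle list gave 0.594, and with the covariate and the block 0.0878.

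Over all genes, limma called 0 genes for both stimuli against IFN-gamma, with 337 genes at an unadjusted p under 0.05, and 0 with the replicate letter as a block, with 839. In both sessions 40 genes were at least 2-fold higher and 11 lower, and 153 changed at least 2-fold in opposite directions. Renewed quantile normalization called 1 gene, CXCL8 (adjusted p = 0.0132), as did leaving out either unstimulated array (0.0495). Without IFN-gamma array A the camera adjusted p was 0.0901 for adhesion genes and 0.268 for oxidative stress genes, which also missed the threshold without either unstimulated array (0.135) and without Borrelia array A (0.0708) or B (0.0762), IFN-gamma array B (0.071) or array A with both stimuli (0.348). The cell cycle list gave 0.549 in the opposite direction without IFN-gamma array B and 0.653 without array A with both stimuli.

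The last comparison asked whether the change with both stimuli departed from the sum of the 2 single changes on the log2 scale. For CXCL8 the departure was 0.00 ± 0.50, with -1.93 on its other probe set, and for SELE 0.23 ± 0.83. It was 0.68 ± 0.56 for CXCL9, 0.41 ± 0.40 for CXCL10 and 0.18 ± 0.43 for CXCL11, whose other probe set gave -0.76. VCAM1 (-1.72 ± 0.84), CXCL2 (-1.28 ± 0.85), IDO1 (-0.90 ± 0.76) and CXCL1 (-0.75 ± 0.58) lay below the sum and CX3CL1 (1.05 ± 0.82) above it, all with an adjusted p of 1. On the linear scale the additive expectation was the unstimulated intensity plus both single increments. The sign turned there for VCAM1, whose mean intensity with both stimuli was 1.40 times that expectation, and for CXCL2, at 1.52 times (3.33 in session A and 0.92 in session B). For CX3CL1 it was 3.27 times. The other probe set of CX3CL1 had a log2 departure of 0.10, beside 1.05 on the probe set tested, and its linear ratio was not computed. The intensity of CXCL8 with both stimuli was 0.55 times its additive expectation (0.79 in session A and 0.36 in session B).

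CCL8 departed by 2.29 ± 0.36 (2.60 in session A and 1.99 in session B), and its mean intensity with both stimuli was 6.25 times the additive expectation on the linear scale. The unstimulated and Borrelia levels of CCL8 lay below the array medians. A Borrelia effect may be hidden there, so the log2 departure may be overstated. CCL8 was the only member of the T cell and monocyte chemoattractants to pass when adjusted over the list alone (adjusted p = 0.00487), and over all genes its adjusted p was 1. In that list 13 of 14 genes lay above the sum, with a median of 0.36 (0.70 in session A and 0.11 in session B; camera adjusted p = 9.85e-05, and adjusted p = 0.248 with an estimated correlation). Without array A with both stimuli the camera adjusted p was 0.191. Limma called 0 genes for the departure, with 62 genes at an unadjusted p under 0.05, and 0 with the replicate letter as a block, with 217. The other settings also called 0.

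The remaining 8 of the 23 lists were not called by camera without a block or covariate in any of the 6 comparisons. Their smallest camera adjusted p-values were 0.059 for coagulation and vascular tone, 0.0667 for the unfolded protein and heat shock response, 0.102 for pattern recognition, 0.153 for complement and 0.233 for angiogenesis and Notch. The smallest adjusted p was 0.671, 0.559, 0.611, 0.44 and 0.445 with an estimated correlation, and over the comparisons 3, 3, 0, 0 and 3 member values passed when adjusted over the list alone. TLR2, the receptor for bacterial lipoproteins, differed by 0.05 ± 0.25 with Borrelia and 0.86 ± 0.25 with both stimuli, with an adjusted p of 1. Tissue factor, F3, differed by 0.24 ± 0.25 with Borrelia, also with an adjusted p of 1. Markers of other cell types gave 0.102 for fibroblasts and smooth muscle, 0.149 for leukocytes and 0.303 for erythroid cells (at the smallest 0.32, 0.391 and 0.58 with an estimated correlation) and no member passed when adjusted over the list alone, with medians across comparisons between -0.09 and 0.12, -0.03 and 0.29, and 0.08 and 0.23.

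Some lists were called, in comparisons where they had not been, once the session or the 3' to 5' difference was in the model. The covariate and its list tests were chosen after the data were seen. With an estimated correlation in the same fits no such call was left. With the block, coagulation genes were lower with both stimuli than with Borrelia (0.0335, and adjusted p = 0.522 with an estimated correlation) and cell cycle genes lay below the sum of the single changes (0.0221, and adjusted p = 0.635 with an estimated correlation; 0.0387 with the covariate as well, and adjusted p = 0.679 with an estimated correlation). With the covariate, complement genes were higher with IFN-gamma, with both stimuli and with both against Borrelia (0.00878, 0.0117 and 0.00304, and adjusted p = 0.28, 0.28 and 0.242 with an estimated correlation). With covariate and block they gave 0.00634, 0.00634 and 0.00485 (adjusted p = 0.413 in each with an estimated correlation). Pattern recognition genes were higher in the same comparisons with the covariate (0.0285, 0.00898 and 0.0012, and adjusted p = 0.511, 0.452 and 0.378 with an estimated correlation). With the block as well they gave 0.119, 0.0452 and 0.0238 (adjusted p = 0.529, 0.467 and 0.461 with an estimated correlation).

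With Borrelia the covariate called MHC class I genes (0.0285), IFN-gamma response genes (0.014) and type I interferon-stimulated genes (0.00409) higher, with adjusted p = 0.666, 0.49 and 0.666 with an estimated correlation. With the block as well they gave 0.0226, 0.021 and 0.00844 (adjusted p = 0.665, 0.607 and 0.653 with an estimated correlation). With IFN-gamma it called NF-kappaB targets (0.000297) and oxidative stress genes (0.0135) higher, with adjusted p = 0.481 and 0.511 with an estimated correlation. With the block as well they gave 0.00634 and 0.0327 (adjusted p = 0.413 and 0.653 with an estimated correlation). Cytokines were higher with both stimuli than with Borrelia (0.0222, and adjusted p = 0.291 with an estimated correlation; 0.0103 with the block as well, and adjusted p = 0.413 with an estimated correlation). MHC class I genes were higher with both than with IFN-gamma (0.0468, and adjusted p = 0.666 with an estimated correlation), but gave 0.0731 with the block as well. Covariate and block together called cytokines higher with IFN-gamma (0.0128, and adjusted p = 0.413 with an estimated correlation) and adhesion genes lower with both stimuli than with Borrelia (0.0481, and adjusted p = 0.679 with an estimated correlation).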

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

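All tests of explanations in this part were chosen after the results were seen. The control probe sets, which the comparisons do not use, set 3 arrays apart. The GAPDH 3' over 5' ratio was 59.68 on IFN-gamma array A, 15.19 on array A with both stimuli and 13.35 on array B with both stimuli, against 3.31 and 1.25 on the unstimulated arrays.

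Values that departed from the sum of the single changes are given next; the interaction called 0 genes. The T cell and monocyte chemoattractants lay above the sum of the single changes by a median of 0.36 (camera adjusted p = 9.85e-05, 0.191 without array A with both stimuli, and adjusted p = 0.248 with an estimated correlation). Of these, CCL8 lay above it by 2.29, which passed when adjusted over the list alone (0.00487) and had an adjusted p of 1 over all genes. The CCL8 levels without IFN-gamma lay below the array medians, so this log2 departure may be overstated. In CXCL1 the change with IFN-gamma was 0.38 and 0.03 in sessions A and B alone and -0.19 and -0.90 with Borrelia, a departure of -0.75 ± 0.58. In ESM1 (endocan) the change with Borrelia was 1.93 and 0.64 alone and -0.30 and -0.53 with IFN-gamma, a departure of -1.69 ± 0.86. Both had an interaction adjusted p of 1, so neither difference is shown. ESM1 was named after its values were seen.

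The first pattern weighed was a set of 271 genes that lay at least 2-fold below the sum of the single changes in both sessions, with a median of -1.43. Their change with both stimuli against none was 0.79 in session A and -1.97 in session B. In session A they also lay above unstimulated cells with Borrelia (1.22) and with IFN-gamma (0.91), against -0.1 and -0.3 in session B. Unstimulated array A had a chip lot of its own. The change of sign therefore cannot decide whether the cells responded alike in both sessions. The 3' to 5' difference departed from additivity by -1.44 in session A and 2.67 in session B. Loss of 5' signal in proportion to it would put genes below the sum in session B, where the set's median was -1.48. It would not do so in session A, where the median was -1.24. The genes were chosen for lying below the sum in both sessions, so the opposite signs cannot decide about session B. Over pairs of 1 array from each session left out, the median was -0.02 without unstimulated array A and array B with both stimuli, 0.03 and 0.09 for the other pairs that left out unstimulated array A, -2.76 to -2.96 for pairs that left out unstimulated array B, and -1.29 to -1.54 for pairs that left out neither. Over these genes unstimulated array A had a median of 5.54 against 6.30 to 6.72 on the other A arrays, and array B with both stimuli 5.66 against 7.31 to 7.62 on the other B arrays. The genes were chosen for this departure on these same arrays, so whether the 2 arrays that stand apart account for it cannot be told apart from other causes.

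The second was a set of 113 genes at least 2-fold lower with both stimuli than with Borrelia alone in both sessions, with a median of -1.61. The shift predicted from each gene's slope on the 3' to 5' difference had a median of -0.21, or 13.4% of the fall. For 16 of the genes it came to 50% of the fall or more. The slope came only from IFN-gamma arrays A and B less the Borrelia arrays, which also chose the genes, and it assumes a proportional effect. The genes' median level was 6.06 on IFN-gamma array A and 6.11 and 6.05 on arrays A and B with both stimuli, which had the high ratios. On the other arrays it was 6.5 to 8.14. The slope therefore cannot decide how much of the fall is due to RNA integrity. On the session B arrays of IFN-gamma and no stimulus, which did not choose the genes, the median change was -0.89 with 104 of the 113 below 0. The medians of 10000 random sets of genes of like mean level centred on -0.14 and went no lower than -0.30. Those sets were drawn gene by gene, so they cannot exclude a shift that the genes share between these single arrays. In session A, where the IFN-gamma array had the ratio of 59.68, it was -0.51 with 84 below 0. An effect of IFN-gamma that does not need the bacterium may contribute, but this is only a hypothesis found on the same data.

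The third was the 13 genes called higher with both stimuli than with Borrelia alone, with a median change of 4.56, since both arrays with both stimuli had a high 3' over 5' ratio. On the session B arrays of IFN-gamma alone and no stimulus, which entered the choice of these genes only through the pooled spread and whose ratios were 1.1 and 1.25, their median change was 4.43 and the lowest 2.57. This argues against loss of 5' signal as the cause of these calls. An effect of IFN-gamma on the cells is the hypothesis that these values leave.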

How the results depend on the processing

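The 3' to 5' covariate, array weights and the fit without the 2 arrays of highest 3' to 5' difference were chosen after the data were seen. With the replicate letter as a block the calls went from 14 to 28 for IFN-gamma, 20 to 68 for both stimuli against none and 13 to 34 against Borrelia, and stayed at 0 elsewhere. By construction the block removes from the spread a session difference common to all groups, which the group with both stimuli did not share. Quantile normalization called 1, 23, 49, 25 and 1 genes for Borrelia, IFN-gamma, both against none, both against Borrelia and both against IFN-gamma. Array weights called 9 for IFN-gamma and 22 for both against Borrelia, and with the block 4, 39, 54 and 49 for the first 4 comparisons. Testing every probe set called 9 for IFN-gamma. The covariate called 10 for both against none, and with the block 7, and 6 against Borrelia. The compared groups alone called 3, 9 and 20 for the 3 comparisons with calls, and the fit without the 2 arrays 0, where fewer arrays were fitted. Leaving out 1 array gave 4 to 12, 4 to 14 and 4 to 18 calls there, and 0 to 1 for both against IFN-gamma. Where no construction is named, the cause was not tested. The interaction stayed at 0 in every fit. The cell cycle list turned direction without an adjusted p under 0.05: for both against none at 0.24 without unstimulated array B and 0.554 with the covariate, against Borrelia at 0.822 with the covariate (with covariate and block it stayed lower, at 0.0241 and 0.00459), and against IFN-gamma at 0.549 without IFN-gamma array B. In its original direction, leaving out 1 array gave it 1.42e-08 to 0.337 against none and 2.36e-06 to 0.653 against IFN-gamma. Of the 45 list shifts, 43 were kept with the block, 39 with the filter, 42 with the trend, 36 with the covariate and 0 with an estimated correlation, where the smallest adjusted p was 0.0868. Of 38 calls of named genes, 38 were kept with the block, 29 with the covariate, and 17 without either array with both stimuli; none turned direction. Signal over background limits what weakly expressed genes can show.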

Other observations

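The genes named here were chosen after their values were seen, and no explanation was tested. At least 2-fold lower with IFN-gamma in both sessions were 27 genes, of which 17 were among the 113 genes so lowered with both stimuli against Borrelia. The 2 comparisons share no array, and independent sets would share 0.15. Independence is a weak reference, since both comparisons hold IFN-gamma arrays of high 3' over 5' ratio. The 113 genes had medians of 6.06 on IFN-gamma array A and 6.11 and 6.05 on arrays A and B with both stimuli. TNFSF15 differed by -2.06 (adjusted p = 0.194), GDF15 by -2.04 (0.561) and THBD, the anticoagulant receptor thrombomodulin, by -1.60 (1), so none was called. At least 2-fold higher with Borrelia in both sessions were 19 genes, of which 12 were among the 40 so raised by Borrelia in the presence of IFN-gamma, where 0.04 would be shared. Across all genes those 2 comparisons correlated with r = -0.03 and the 2 IFN-gamma comparisons with r = 0.46 (across genes, which are not independent replicates).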
